A study of Mus musculus with 4 samples.

How the data were processed

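RNA from whole mouse liver was measured on 4 Agilent 2-colour arrays of 1 slide, each hybridised with RNA labelled AAV_Cre in 1 dye and RNA labelled AAV_Null in the other. AAV_Cre was in Cy5 on arrays 1 and 2 and in Cy3 on arrays 3 and 4, and each RNA was hybridised once, per the labels. All arrays came from 1 slide, so no slide effect was fitted. The labels' protocols give 2 labelling procedures, a reverse transcription from a larger input and a low input kit with 200 ng of RNA, and which was used was not settled here.

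The spot intensity of both dyes and its local background were read by Agilent Feature Extraction 11.5.1.1, per the file headers. Its processed intensity was background-subtracted and dye-normalised within the array, and its log10 ratio of Cy5 over Cy3 was derived from that, per the file headers. A table of log2 values was also deposited, and limma is named in the submitters' processing notes without a version or its steps. Over spots with both processed signals above 2000, these log2 values had a slope against the scanner log10 ratio of 3.34, 3.33, -3.29 and -3.39 on arrays 1 to 4, where the log2 of 10 is 3.32. The table is therefore on a log2 scale, with AAV_Cre over AAV_Null on each array under the labels' dyes. Its medians were -0.02, -0.04, 0.04 and 0.04, and its normalisation steps stay unknown. It held 43173 rows, of which 2 were not in the scanner files and were not used.

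The analysis started from the mean spot intensities and median local backgrounds. Background was corrected with normexp at an offset of 50, and each array was normalised by loess with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Spots marked as outliers by the scanner software were left out, unless a probe would have lost its spots on all 4 arrays. Spots of 1 probe were averaged. Of 39429 probes, 20585 were well above background in at least 3 of the 4 AAV_Cre channels or at least 3 of the 4 AAV_Null channels, and 20335 of these had an unmarked spot on at least 3 arrays with both orientations present. The log2 ratio was fitted with a dye effect and a treatment effect by lmFit and eBayes, which left at most 2 residual degrees of freedom per probe beside 2.67 prior degrees of freedom. A gene was represented by its probe of highest mean intensity, and p-values were adjusted by Benjamini-Hochberg over 16079 genes, with 0.05 as the threshold. The 4 arrays limit the precision, and the median standard error of a log2 ratio was 0.06. The labels do not say whether each RNA came from 1 animal or from a pool. The p-values measure the spread between arrays of the same dye orientation. Any difference between the RNA pairs of arrays 1 and 2 and those of arrays 3 and 4 is taken up by the dye effect, and the SE do not hold it.

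Symbols were updated through a RefSeq table of assembly GRCm38.p6, used for names alone. It named 27508 probes by accession and 404 by a synonym, 3544 had a current symbol, and 7973 kept the array's name. Coordinates are those of the array files, on mm9.

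Before the data were examined, 28 gene lists, the named-gene rule and the alternatives were fixed. Lists were tested with limma's camera at a preset correlation of 0.01 and adjusted over the 28 lists, with an estimated correlation and fry as alternatives. Named genes were Trib1 and Cebpa, the 12 highest and 12 lowest log2 ratios among called genes with the same sign on 4 of 4 arrays (clone and predicted names left out), and per list up to 4 called members of largest change, or the member of smallest p where none was called. The rule gave 72 genes, of which 1 is not reported here. Other genes given below are list members printed to describe a count, chosen after their values were seen.

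The fit was tested on simulated data for 15701 genes with the fitted dye effects and spread, with 200 genes changed in each of 40 draws. It recovered 38.5% of changes of 0.5 on the log2 scale, 90.4% of changes of 1 and 98.5% of changes of 2. On average 4.86% of calls were false, with a range over draws of 1.37% to 10.1%. The simulated spread followed the variance model that the fit assumes, so these shares do not measure false calls among the real genes. In 1 simulated set of lists of 20 genes shifted by 0.4, camera found 6 of 6 shifted lists at the preset correlation and 0 of 6 with an estimated one, and called 0 of 22 unshifted lists either way. The noise was drawn independently for each gene, so these lists do not test the preset where members move together.

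The alternatives were no dye effect, a separate-channel fit (statmod 1.5.0), other background corrections and normalisations, other filters, outlier spots kept, other treatment of several probes, other empirical Bayes settings, array weights, the authors' deposited log2 values, other thresholds and each array left out. Probe sequences were aligned with Biostrings 2.70.1, and figures were drawn with matplotlib 3.10.9.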

Results

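Livers of female C57B/6 mice of 8 to 10 weeks, homozygous for a floxed allele of Trib1, were compared 1 week after an adeno-associated virus that carries Cre (AAV_Cre) or a control virus (AAV_Null), after a fast of 4 hours. Cre recombinase removes sequence between loxP sites. The study asked what loss of hepatic Trib1, a pseudokinase that brings C/EBPα to the COP1 ubiquitin ligase, does to liver gene expression and lipid synthesis. There were 4 arrays, each with 1 RNA of each treatment. Each array held 43020 spots that were not controls. Between 51.0% and 55.3% of spots in Cy5 and between 53.1% and 58.7% in Cy3 were well above background, and 0 spots were saturated. The log2 ratios of AAV_Cre over AAV_Null correlated across genes at 0.67 between arrays 1 and 2 and at 0.48 between arrays 3 and 4, against 0.07 to 0.19 between arrays of opposite dye orientation. Genes are not independent replicates. A dye effect passed an adjusted p of 0.05 in limma for 388 probes, and it was fitted for every probe.

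Trib1 itself was not lower in RNA labelled AAV_Cre. The RefSeq probe that stood for the gene, at chromosome 15, 59487475 to 59487534 (mm9), had a log2 ratio of 0.94 ± 0.08 (SE, n = 4 arrays), or 1.92-fold, at an adjusted p of 0.0204 in limma, and was higher on 4 of 4 arrays. A second probe of the same transcript, at 59487662 to 59487721, had 1.29 ± 0.11 (SE, n = 4) at an adjusted p over probes of 0.0233. A probe at lower coordinates, 59485136 to 59485195, assigned to an Ensembl transcript, had -0.047 ± 0.049 (SE, n = 4) at an adjusted p of 0.615. The RefSeq probes start at bases 2846 and 3033 of their transcript. They go against the label only if the deletion removes the sequence they measure. The labels do not say which part of Trib1 is floxed, and a probe outside the deleted part checks nothing. Directions below are those of RNA labelled AAV_Cre over RNA labelled AAV_Null, and the authors' deposited log2 values gave Trib1 0.95 in the same direction.

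**Figure D1:**
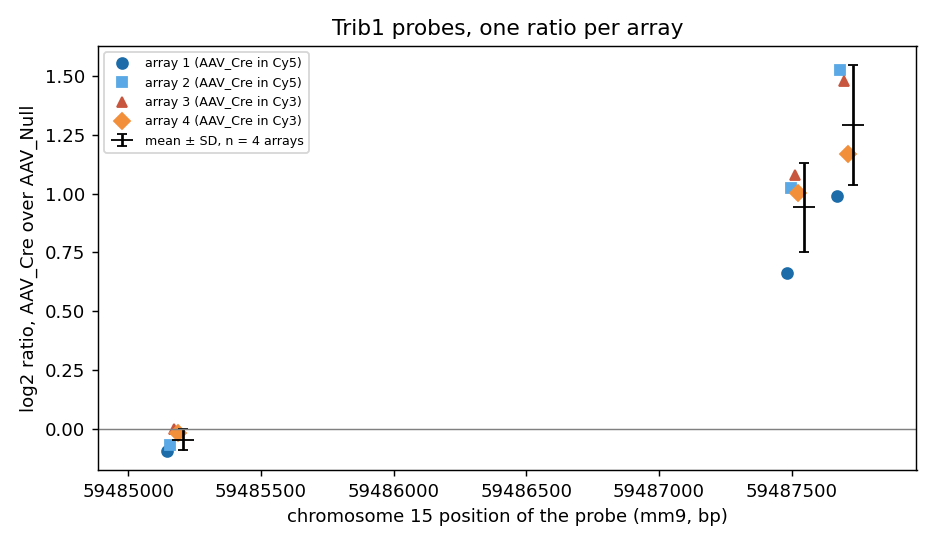
Log2 ratio of AAV_Cre over AAV_Null for the 3 Trib1 probes (vertical axis) against their mm9 position on chromosome 15 in bp (horizontal axis), with 1 point per array, spread sideways, and the mean ± SD of 4 arrays. Both RefSeq probes lie above 0 on each array, and the probe at lower coordinates lies near 0.

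Of 16079 genes, 451 differed between the treatments, 294 higher and 157 lower in RNA labelled AAV_Cre. Sult1e1, estrogen sulfotransferase, rose most among the named genes, by 2.79 ± 0.10 (SE, n = 4 arrays) on the log2 scale or 6.90-fold, at an adjusted p of 0.00831. Sult3a2 rose by 2.46, and the hydroxysteroid sulfotransferases Sult2a4, Sult2a3, Sult2a7 and Sult2a1 rose by 2.23, 2.16, 1.90 and 1.75. Phlda3, Ly6d, Atp8b5, Clstn3, Lrtm1 and Olig1 rose by 2.28, 1.96, 1.92, 1.76, 1.65 and 1.59. Nox4, an NADPH oxidase, fell by 2.36 ± 0.08 (SE, n = 4) at an adjusted p of 0.00767, and Slc22a7, an organic anion transporter, fell by 2.14. Enho, which encodes adropin, fell by 2.04, and its 2 probes had -2.23 and -2.04. Gas2, Slc22a27, Cyp2c23, Clec2h, Cyp2d40, Rgs3, Cebpe and Limd2 fell, with log2 ratios of -1.55, -1.41, -1.33, -1.29, -1.19, -1.14, -1.11 and -1.11, and Nat8f1 fell to 0.467 of the AAV_Null level. The naming rule required these 24 genes to have the same sign on 4 of 4 arrays. Of the 451 called genes, 445 had the same sign on the arrays that measured them.

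Probes of 1 gene did not always move together. A second probe of Atp8b5 had -0.04, other probes of Nox4 reached -0.19, and other probes of Limd2 reached 0.12. Second probes of Cdkn1a and Cul4b had 0.41 and -0.073, the latter for the same transcript. For Rgs3, a second probe of the same transcript was measured on arrays 3 and 4 alone, at -0.16 and -0.27, and the gene's value turned to 0.14 when spots marked as outliers were kept. The Sult2a1 probe shares 54 of 60 bases with that of Sult2a2, and the Sult2a4 probe shares 51 with that of Sult2a1, so these signals are uncertain as to which copy they measure. The Sult2a3, Sult2a6 and Sult2a7 probes share 23, 13 and 9 bases with their closest other Sult2a probe. Probes were aligned with each other and not with the transcripts of the other copies, so few shared bases do not show that a probe measures 1 copy. Sult2a6 had 1.68, while Sult2a8 had -0.85. The count of 451 rested on all 4 arrays, with 14, 0, 38 and 5 genes past the threshold when arrays 1, 2, 3 and 4 were left out. Each array left out leaves 3 arrays and 1 fewer residual degree of freedom. Over 4 arrays a sign permutation test cannot go below a two-sided exact p of 0.125.

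**Figure D2:**
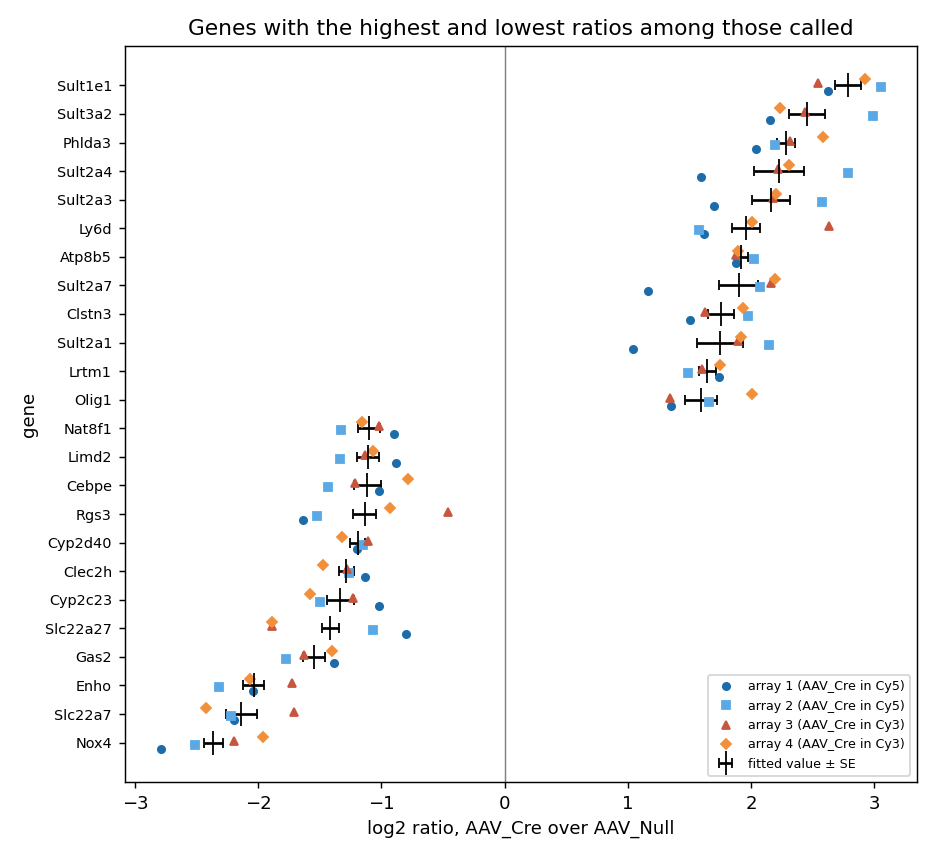
Log2 ratio of AAV_Cre over AAV_Null (horizontal axis) for the 12 highest and 12 lowest named genes (vertical axis), with 1 point per array and the fitted value ± SE as a black mark. Sult1e1 at 2.79 and Nox4 at -2.36 are the ends of the range.

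Several genes of fatty acid synthesis rose. Of 20 measured members 7 rose, 0 fell and 13 did not pass, and adjusted over the list alone 9 rose and 2 fell. Pnpla3, a lipid droplet hydrolase, rose by 1.25 ± 0.14 (SE, n = 4), Scd1, the stearoyl-CoA desaturase, by 0.99 ± 0.11, and Fasn, fatty acid synthase, by 0.80 ± 0.07. The Pnpla3 probe was dim, at a mean log2 intensity of 7.49, and a second probe of its transcript had 0.71. Me1, malic enzyme, rose 2.15-fold. Thrsp, G6pdx and Pgd rose by 0.76, 0.64 and 0.38. Acly at 0.19 and the regulator Srebf1 at 0.01 did not pass. The list's median was 0.29, at an adjusted p of 0.000451 by camera, of 0.693 with an estimated correlation and of 0.127 by fry.

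Some genes of triglyceride synthesis and lipid droplets also rose. Of 20 measured members 4 rose, 0 fell and 16 did not pass, and adjusted over the list alone 6 rose and 0 fell. Cidec, a lipid droplet fusion protein, rose by 1.39 ± 0.10 (SE, n = 4), Cd36, a fatty acid transporter, by 1.18 ± 0.06, Mogat1, a monoacylglycerol acyltransferase, by 0.93 ± 0.13, and Fitm1 by 0.66 ± 0.06. The list's adjusted p was 3.35e-05 by camera, 0.859 with an estimated correlation and 0.140 by fry. Genes of cholesterol synthesis and uptake were lower as a list, with a median of -0.17 and an adjusted p of 0.00866 by camera, 0.946 with an estimated correlation and 0.456 by fry. Idi1, isopentenyl-diphosphate isomerase, fell by 0.50 and was the 1 member of 23 to pass, also adjusted over the list alone. Without array 1 the cholesterol list had an adjusted p of 0.506, and without array 3 of 0.0515. The correlation between genes was estimated at 0.399 in the triglyceride list and 0.498 in the cholesterol list, against the preset 0.01. The p by camera at the preset are therefore too small if members of these lists move together.

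Other lipid lists did not pass as lists. Among 24 genes of lipoprotein assembly and clearance, Abcg5, a sterol exporter, rose by 0.47 and Apoa2 fell by 0.36, with 4 rising and 5 falling adjusted over the list alone (list adjusted p = 0.983). Apoa2 had a ratio above 0 on arrays 1 and 2 and below 0 on arrays 3 and 4. Among 26 genes of fatty acid oxidation and ketogenesis, the microsomal omega-hydroxylases Cyp4a14 and Cyp4a10 fell by 1.31 and 0.64, with 1 rising and 3 falling adjusted over the list alone (list adjusted p = 0.564). Among 19 genes of bile acid synthesis and transport, Amacr and Slc27a5 fell by 0.52 and 0.35, with 5 rising and 4 falling adjusted over the list alone (list adjusted p = 0.790).

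Several targets of p53 rose. Of 18 measured members 9 rose, 0 fell and 9 did not pass, and adjusted over the list alone 11 rose and 1 fell. Phlda3 rose by 2.28 ± 0.07 (SE, n = 4), Cdkn1a, the cyclin-dependent kinase inhibitor p21, by 1.46 ± 0.11, Ccng1 by 1.01 ± 0.07 and the death receptor Tnfrsf10b by 0.93 ± 0.07. The other 5 that rose were Aen, Zmat3, Plk2, Mdm2 and Bax, between 0.61 and 0.93. Plk3 had -0.39 and was the member that fell adjusted over the list alone, and Bbc3 at -0.11 and Pmaip1 at -0.078 did not pass. The list's median was 0.73, at an adjusted p of 6.05e-07 by camera and of 0.470 with an estimated correlation. Its median on single arrays lay between 0.65 and 0.87.

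Some female-biased and some male-biased liver genes rose, in female mice. Both lists were higher by camera, with an adjusted p of 0.000208 for the female-biased and 0.000171 for the male-biased list, and 0.470 for each with an estimated correlation. Of 17 measured female-biased genes 5 rose, 1 fell and 11 did not pass, and adjusted over the list alone 8 rose and 2 fell. Sult2a2 rose by 2.06 ± 0.07 (SE, 3 arrays) and Sult2a1 by 1.75, while Cyp4a14 fell by 1.31. Of 17 measured male-biased genes 6 rose, 0 fell and 11 did not pass, and adjusted over the list alone 10 rose and 2 fell. The 2 that fell were Slco1a1 at -0.73 and Hsd3b5 at -0.58 ± 0.10 (SE, n = 4), and Cyp2d9 at 0.02 did not pass. Elovl3 rose by 1.21 ± 0.11 (SE, n = 4), Cyp4a12b by 1.08 ± 0.08, the major urinary protein Mup21 by 0.82 ± 0.06 and Susd4 by 0.74 ± 0.09. On arrays 1 to 4 Cyp4a12b had 0.37, 0.77, 1.52 and 1.64, Susd4 had 0.54, 0.050, 1.22 and 1.16, and Hsd3b5 had -1.21, -1.35, -0.13 and 0.37. The fitted dye effect takes up this split by orientation, so these SE do not hold it. The calls of Slc22a27 (-0.80, -1.07, -1.89 and -1.89 on arrays 1 to 4), Apoa2 and Trf rest on such SE too. Cyp2b9, Cyp2b13 and Cyp3a16 are in both the female-biased and the xenobiotic list. Among 25 genes of xenobiotic metabolism, Sult1e1, the nuclear receptor Nr1i2 (0.50) and Cyp2b13 (0.48) rose, and Cyp2c29 (-0.43) and Cyp2c37 (-0.41) fell, with 6 rising and 7 falling adjusted over the list alone (list adjusted p = 0.790).

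Cebpa, the transcription factor named in the study's title, fell at the RNA level by 0.59 ± 0.06 (SE, n = 4) or to 0.666 of the AAV_Null level, at an adjusted p of 0.0301, and was lower on 4 of 4 arrays. In the list of Tribbles, COP1 ligase and C/EBP genes, Trib1 rose and Cebpa, Cebpe (log2 ratio -1.11, adjusted p = 0.0242) and Cul4b fell among 14, with 2 rising and 4 falling adjusted over the list alone. Cul4b, a cullin scaffold, fell by 0.38 on 1 of its 2 probes. The list's adjusted p was 0.824. Protein was not measured on these arrays.

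Few glucose, amino acid and clock genes passed, and none of their lists did. Among 16 genes of gluconeogenesis and glycogen, Gpt2, a mitochondrial alanine aminotransferase, rose by 0.57, with 2 rising adjusted over the list alone (list adjusted p = 0.983). Among 15 glycolysis genes none passed in limma over all genes or adjusted over the list alone, and Khk had 0.23 (list adjusted p = 0.824). Among 28 genes of amino acid catabolism and the urea cycle, Sds and Sdsl, serine dehydratases, fell by 0.51 and 0.50, the same 2 adjusted over the list alone (list adjusted p = 0.535). Among 16 clock genes, the repressor Nfil3 rose by 0.77, also adjusted over the list alone (list adjusted p = 0.376). Among 20 genes of the unfolded protein and integrated stress response, 0 passed over all genes and 2 rose adjusted over the list alone, and Edem1 had 0.47 (list adjusted p = 0.983). Among 20 cell cycle genes, Rrm2, a ribonucleotide reductase subunit, rose by 0.50, also adjusted over the list alone (list adjusted p = 0.252).

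Among markers of other liver cells, the stellate list was higher and the endothelial list lower by camera at the preset correlation. Of 15 stellate cell and matrix markers, Col3a1, a fibrillar collagen, rose by 0.47 ± 0.06 (SE, n = 4), and 6 rose adjusted over the list alone. The list's median was 0.23, with an adjusted p of 0.000451 by camera, 0.693 with an estimated correlation and 0.182 by fry. Of 17 endothelial markers 0 passed over all genes, and 1 rose and 7 fell adjusted over the list alone. Their median was -0.15, with an adjusted p of 0.000588 by camera, 0.470 with an estimated correlation and 0.127 by fry, and Clec4g had -0.35. The endothelial medians were -0.0010, -0.028, -0.28 and -0.31 on arrays 1 to 4. Of 15 hepatocyte markers Trf, transferrin, fell by 0.51 and 4 fell adjusted over the list alone (list adjusted p = 0.223). Trf had ratios above 0 on arrays 1 and 2 and below 0 on arrays 3 and 4.

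No member of the acute phase, interferon-stimulated, macrophage, T and natural killer cell, B cell, neutrophil, cholangiocyte or erythroid lists passed in limma, over all genes or adjusted over the list alone. These lists held 25, 24, 19, 12, 9, 8, 7 and 5 measured genes, and over all 16079 genes 3631 had an unadjusted p under 0.05. The member of smallest p had a log2 ratio of 0.31 for Hamp, -0.49 for Cxcl10, -0.59 for Marco, 0.21 for Cd3d, 0.14 for Cd79a, -0.15 for Csf3r, 0.22 for Sox9 and -0.33 for Hbb-b2. The lists' adjusted p was 0.824, 0.223, 0.0594, 0.944, 0.564, 0.475, 0.740 and 0.790. In 5 of the 28 lists, none of them called, the median, the mean and the test differed in sign: lipoprotein, gluconeogenesis, Tribbles and C/EBP, unfolded protein response and erythroid genes. The acute phase list had medians of -0.22, 0.012, 0.45 and -0.45 on arrays 1 to 4, and the interferon-stimulated list had 0.55 on array 3 and -0.26, -0.37 and -0.53 on arrays 1, 2 and 4. By camera at the preset correlation of 0.01, the interferon-stimulated and macrophage lists were lower in RNA labelled AAV_Cre without array 3, with adjusted p of 8.71e-10 and 2.54e-08, while the interferon-stimulated list was higher without array 4, with an adjusted p of 0.0201. Over all 4 arrays the correlation between genes was estimated at 0.794 and 0.798 in these lists, far above the preset, so such p are too small if members move together, and with it the adjusted p was 0.946 for each.

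**Figure D3:**
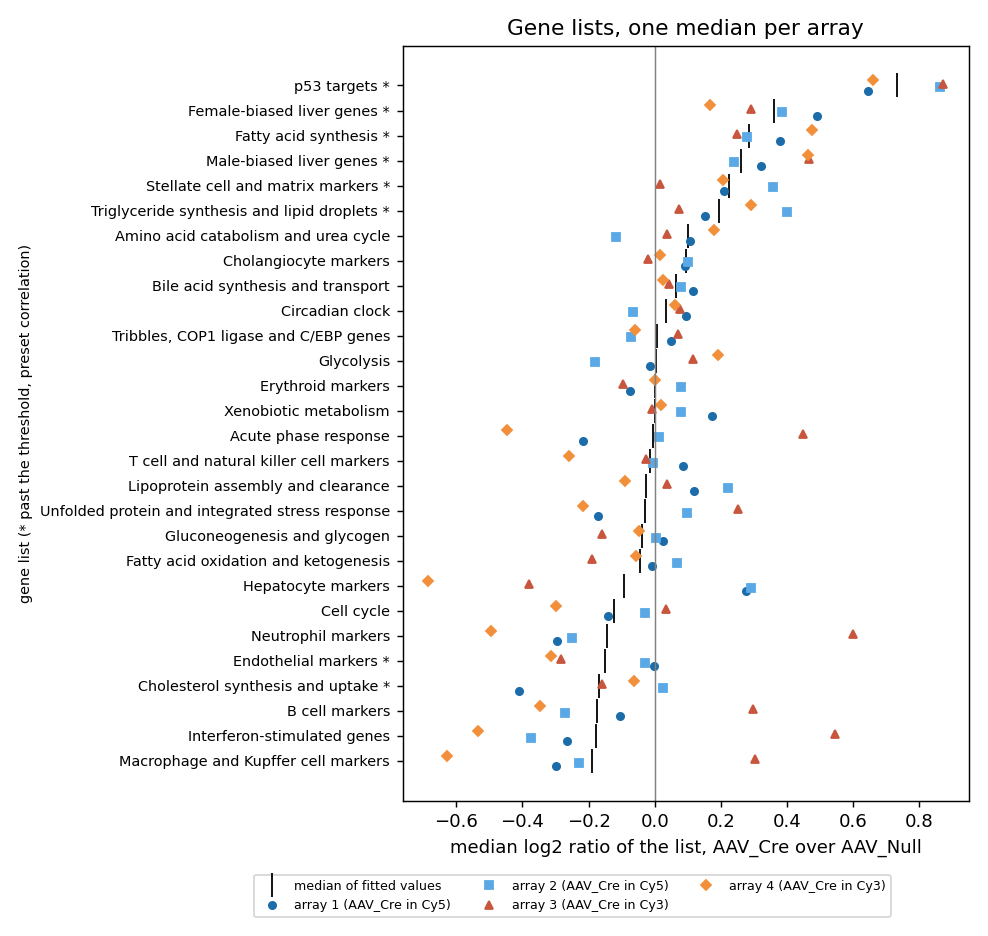
Median log2 ratio of AAV_Cre over AAV_Null (horizontal axis) for each of the 28 gene lists (vertical axis), with 1 point per array, the median of the fitted values as a black mark, and a star where camera at the preset correlation passed. The p53 list lies between 0.65 and 0.87 on the arrays, while the interferon-stimulated, neutrophil, macrophage, B cell and cell cycle lists lie above 0 on array 3 and below 0 on the other 3 arrays.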

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

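The tests in this part of exchanged RNAs on single arrays, on all arrays and on array 3, of probe position, of immune cells and of a Cre effect were chosen after the result was seen. Of 98 named genes and list medians measured on 4 arrays, 3 had 1 array far from the other 3, where chance gives about 4.9. The ratios tested still held the dye effect, which can part arrays 1 and 2 from arrays 3 and 4. Such a split can hide 1 array apart, so the 4.9 is a rough guide. Atp8b5 had 2.03 on array 2 against 1.88 to 1.90 on the others. Sult2a7 had 1.16 on array 1 against 2.08 to 2.19. Ccng1 had 1.25 on array 4 against 0.91 to 0.95.

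Trib1 was higher in RNA labelled AAV_Cre on both RefSeq probes, the opposite of what the label would give for a deleted transcript. An exchange of the RNAs on a single array is argued against, since of the 500 genes with the smallest p on the other 3 arrays at least 77.5% kept their sign on the array left out, the lowest being array 3. The test was first written for called genes, which were too few (14, 0, 38 and 5). An exchange on all 4 arrays cannot be told apart from the labels by a ratio of 0.94 with no other gene that marks the treatment. Deletion upstream of these probes stays open too, and the probe at lower coordinates cannot settle it. That probe is assigned to another transcript, at its base 2972, while the RefSeq probes start at bases 2846 and 3033 of theirs. It may therefore not report on the RefSeq transcript. It had -0.047 with an adjusted p of 0.615 in limma, which passes a first-written bound of 1 SD (0.044) but not the test used in its place. That probe was also dim, at a mean log2 intensity of 7.64.

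The rise of several p53 targets was weighed against immune cells and against a single array. On the 3 arrays where the macrophage list's median was below 0, the p53 list's median was at least 0.65, with an SD of 0.12 over arrays, which argues against more immune cells as the source. With each array left out in turn the list's adjusted p was at most 6.47e-07, so no single array carried it. An effect of Cre or its vector apart from Trib1 stays open for the 9 genes that rose, because no group had Cre without the floxed gene, and so does loss of Trib1 as a biological explanation, untested.

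The acute phase, interferon-stimulated and macrophage lists had their highest median on array 3. An exchange of its RNAs is argued against by the same 77.5% of genes that kept their sign there. Over 66 genes of the 3 lists, the AAV_Cre RNA of array 3 had a median level of 0.31 on the log2 scale from the mean of the 8 RNAs, against -0.08, -0.27 and -0.26 for the other AAV_Cre RNAs, which is consistent with 1 AAV_Cre RNA of higher level. Taken singly, after the test, its gap to the next AAV_Cre RNA exceeded the range of the other 3 for the interferon-stimulated list (0.46 against at most -0.20), but not for the acute phase (0.22 against at most 0.020) or macrophage list (0.30 against at most -0.053). The AAV_Null RNA of array 3, at 0.011, lay within the range of the others (0.08, -0.18 and 0.42), so a low AAV_Null RNA is argued against over the 3 lists together, though for the acute phase list alone it was the lowest, at -0.13, and stays open. The AAV_Null RNA of array 4 was high, at 0.42. No biological explanation was tested, since the labels give no difference between the animals.

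Chance was not settled for the 451 genes: 7 sign patterns of the 4 arrays can be fitted beside the dye effect, too few for a share under 0.05. The real pattern called 451 genes and was the 1 pattern to reach that count, and the highest of the others called 0. Under the other patterns a real treatment difference would be left in the residual spread, so their count of 0 is no measure of chance.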

How the results depend on the processing

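The other Trib1 probes were tried after seeing the data. Of 1132 values of the other named genes under settings that kept all arrays, 1033 kept their side of the threshold, with direction kept for called genes. Of the 958 values of called genes 75 lost the call, 23 of uncalled genes gained it and 1 turned. The 1 that turned was Rgs3, at 0.14 with outlier spots kept, where another probe stood for the gene. With each array left out, 202 of the 234 values of called genes lost the call, as fewer arrays leave less to estimate the spread. Uncalled results changed sign 39 times over all alternatives, and these were counted as unchanged, not as turned. Aquantile after loess changes no ratio, so it moved nothing. The counts moved with the offset and with no filter, where 29983 genes were tested in place of 16079. In the reported results, signal over background limits the tests to the 20585 of 39429 probes that passed the filter. The cause was not tested for the changes below unless one is given. The fit on ratios within an array is already paired by array, and the dye orientations share no replicate number, so no further block was fitted.

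The 451 changed genes (294 higher, 157 lower) became 1307 (769 and 538) at an adjusted p of 0.10, 12 (9 and 3) at 0.01 and 68 (49 and 19) with at least a 2-fold change. They became 286 (88 lower) with no dye effect, 2511 (1306 and 1205) in the separate-channel fit, 1412 (841 and 571) with no background correction, and 200 (140 and 60) with a normexp offset of 16. They became 728 (458 and 270) with the scanner's processed signals, 765 (535 higher) with median centring, 288 (89 lower) with no filter, 1470 (828 and 642) with an intensity trend and robust prior, and 1382 (827 and 555) with the authors' deposited values. Of the 451, 442 were also called in the separate-channel fit, 438 from the authors' values and 198 at the offset of 16. With each array left out, between 0 and 38 genes were called, 0 to 23 higher and 0 to 15 lower, and limma gave 0 without array 2, where 2111 had an unadjusted p under 0.05.

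Trib1 lay between 0.85 and 1.03 with each array left out and lost the call each time, and had -0.047 on the probe at lower coordinates.

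With an estimated correlation, 0 of 28 lists passed. The adjusted p was then 0.693 for fatty acid synthesis, 0.859 for triglyceride synthesis, 0.946 for cholesterol, 0.470 for the female-biased, male-biased, p53 and endothelial lists, and 0.693 for stellate markers. On simulated lists this setting found none, but their genes were drawn independently. In the called lists the estimated correlation ran from -0.061 (male-biased) to 0.498 (cholesterol). The simulation therefore cannot tell how much of the loss of calls is low power and how much is members that move together. For the female-biased and male-biased lists the estimates, -0.060 and -0.061, lay below the preset correlation of 0.01. These values argue against members that move together as the source of the loss in these lists. The estimate for endothelial markers, 0.015, lay just above the preset. The other called lists had 0.067 (p53) to 0.498 (cholesterol), and for them the question stays open. By fry, which asks whether a list moves one way, the adjusted p was 0.127 for fatty acid synthesis, 0.140 for triglyceride synthesis, 0.456 for cholesterol, 0.182 for stellate and 0.127 for endothelial markers, and the other 3 called lists passed.

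The macrophage list passed with no dye effect (adjusted p 0.0204), median centring (0.00397), no filter (0.00467), the strict filter (0.0425) and array weights (0.0444), and the interferon-stimulated list with median centring (0.0164). The cholesterol list did not pass in the separate-channel fit (0.0754). With each array left out the adjusted p by camera at the preset correlation ranged from 1.97e-06 to 0.506 for cholesterol, 7.33e-05 to 0.919 for acute phase, 8.71e-10 to 0.347 for interferon-stimulated, 0.0132 to 0.909 for cell cycle, 0.00407 to 0.549 for hepatocyte, 2.54e-08 to 0.864 for macrophage, 0.0103 to 0.909 for B cell and 0.000461 to 0.659 for neutrophil genes. All of these but cholesterol passed without array 3, lower in RNA labelled AAV_Cre, and the interferon-stimulated list turned higher without array 4, at 0.0201.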

Other observations

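Other called genes, chosen here after their values were seen, lie outside the fixed lists. Gadd45a, a stress-induced gene, rose by 1.29 on the log2 scale, Ddias by 1.40 and the DNA repair enzyme Mgmt by 0.79. The receptor genes Tgfbr2 and Erbb4 rose by 1.56 and 1.07, and Serpina7, thyroxine-binding globulin, by 1.54. Major urinary protein genes Mup2, Mup9 and Mup19 rose by 1.02, 1.11 and 0.99, and these near-identical copies cannot be separated with certainty by probes. The organic anion transporters Slc22a26 and Slc22a29 fell, with log2 ratios of -0.99 and -0.69, as did Prdx4 (-1.05), Abca8b (-1.05) and Adh4 (-0.92).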
